A study of Mus musculus with 25 samples.

How the data were processed

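ChIP-seq with antibodies to the Rpb1 carboxy-terminal domain (Pol II), H3K4me3, H3K27ac, H3K4me1 and H3K27me3 was done in 32D, wild-type mast cells, WSH mast cells, MC9 and MC9 shRad21, with 1 library per cell type and antibody and 25 libraries in all. The submitters' processing notes name cutadapt 1.9.1, BWA 0.7.13 and the mouse build mm10, without saying what each did. How the values were normalized is not given in the sources used here. The files hold values over 2 kb bins that tile the genome, over 9322 CpG islands widened at both ends and named by gene (9012 genes, median length 1090 bp). Others hold values over whole transcripts and over the transcribed region downstream of each island (median 28908 bp), all with 1-based mm10 coordinates.

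The deposited values are called signal here. In 1 reference library per antibody they are read coverage per base relative to the genome mean, as read from the values themselves. All libraries of an antibody share a maximum, and 100.00% of the values of 1 library per antibody are whole multiples of 1 read within 0.01. Bin means of these 5 libraries lie between 0.986 and 1.01, and those of the others run from 0.648 to 1.49. The authors thus appear to have adjusted each library to the ranks of a reference library (wild-type mast cells, and WSH mast cells for H3K27ac), which sets equal ranks to equal values and so hides differences in the spread of a mark between cell types. Signal of the other libraries is thus on the scale of the reference and need not be a multiple of their own genome mean. For example, the Fuk island in MC9 has an H3K27me3 signal of 16.0, but 3.32 times the genome mean in reads. The deposited H3K27ac values of MC9 shRad21 are a score, since 63114 of its bins (4.64%) lie below 0. Because the adjustment keeps ranks, whole reads per bin were recovered by rank from the 2 kb files of each library. In the reference libraries, where the answer is known, 99.973 to 99.997% of bins came out exactly. The other libraries could not be checked in this way. Above the lowest read number that no bin holds, a rank gives only a lower bound. Read counts of islands cover every bin an island overlaps, so they take in flanking sequence that the deposited island values leave out, and 8 islands overlap no bin and so have no read count. A feature can therefore be listed at 0 and hold reads. No read was placed on chromosomes X, Y or M in any library (131395 bins). With these included, 144020 bins (10.59%) held no read in any library. The genome mean of reads was taken over all bins, so multiples of it lie higher than over covered bins alone. The antibodies' depth ran from 1615826 to 14812803 recovered reads, and the floor for a feature without reads was set at 3 counts. Duplicate reads could not be told from separate molecules, so intervals and floors cover counting error only.

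Comparisons were wild-type mast cells over 32D, MC9 over 32D, WSH over wild-type mast cells, MC9 shRad21 over MC9, and MC9 over wild-type mast cells. For each, log2 ratios were taken of signal plus a pseudocount, the 25th percentile of the features (Pol II downstream of islands 0.675, H3K27me3 at islands 0.554, H3K4me3 at islands 6.30). Features at or above the median in either library (1.72, 1.12 and 28.5) were counted when they differed 2-fold. With 1 library per group no test across genes was made and no p-value is given. Ratios of reads scaled by library total carry exact 95% intervals (Clopper-Pearson on the conditional binomial share), and counting noise was estimated from 100 simulated pairs of libraries without a difference. H3K27me3 was related to Pol II by Spearman's rho across islands and by medians in 20 rank bins of Pol II downstream. Distal H3K27ac bins were those in the top 1% for H3K27ac and the top 5% for H3K4me1 and more than 2 kb from an island, so they include promoters without one (of the bins gained, 666 of 6620 between wild-type mast cells and 32D, 735 of 6635 between MC9 and 32D and 207 of 1395 between MC9 shRad21 and MC9 lay within 2 kb of a gene's 5′ end). Distal bins of the first cell type of a pair were called gained when H3K27ac there was at least 2-fold higher than in the other. Those of the other cell type were called lost when H3K27ac was at least 2-fold lower in the first. A gained or lost bin can thus reach the top shares in both cell types.

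There were 16 gene lists: mast cells, neutrophils and monocytes, blood progenitors, developmental Polycomb targets, housekeeping, Polycomb machinery, cohesin and CTCF, interferon response, cell cycle, T and natural killer cells, B cells, erythroid cells and megakaryocytes, macrophages and dendritic cells, basophils and eosinophils, stroma and endothelium, and the 37 genes around Kit. List values were Pol II over the whole transcript and H3K27me3 and H3K4me3 within 1000 bp of the 5′ end (pseudocounts 0.491, 0.542 and 0.615, filters 1.49, 0.977 and 4.43). Each list's median was placed among the medians of 10000 random lists of the same size and matched mean level drawn from 18583 autosomal protein-coding genes, as a description of these libraries. Names were matched through a RefSeq gene table, which held 8839 of the island genes. Genes named in the text were, among features above the 75th percentile in either library, the 6 highest and 6 lowest in Pol II and the 5 highest and 5 lowest in H3K27me3 per comparison. Named too were the 5 islands highest in H3K27me3 per cell type, members of each list with the largest differences, and Kit and Rad21. Some genes that this rule names are not reported here. The groups, comparisons, lists, naming rule, pseudocounts, filters and the first group of other settings below were set before the data were examined.

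The other settings set in advance were Pol II over the island or the whole transcript, only islands above 0, no filter on low values, islands split in 3 by Pol II, a pseudocount at the 10th percentile, the top 0.5% of H3K27ac, and quantile normalization. Recovered reads, leaving out X and Y, islands with every bin covered and a subtracted 4 Mb regional level were chosen after seeing the data. Reads were simulated for MC9 over wild-type mast cells with 9322 features. In these, 4-fold changes were found at 100 of 100 raised and 93 of 100 lowered Pol II features, with 3 unchanged features called. At H3K27me3 islands they were found at 100 and 75 of 100, with 80 unchanged called. The simulation used reads scaled by library total, so it does not measure the error of counts from the deposited signal. The changed features were drawn from those at or above the median read density, so weakly covered features were not assessed. Intervals held the true ratio at 96.0% of these changed features. A peak put in bin 5 was found in bin 5, and 9 of 200 lists without effect fell outside percentiles 2.5 to 97.5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. No genome sequence was used here, so mappability and base composition were not analysed here.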

Results

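The series profiled RNA polymerase II (Pol II, antibody to the carboxy-terminal domain of Rpb1) and the histone marks H3K4me3, H3K27ac, H3K4me1 and H3K27me3 by ChIP-seq in 5 kinds of mouse cell grown with interleukin-3. These were 32D, a myeloid cell line; mast cells grown from wild-type mice; mast cells from WSH mice, which carry a chromosomal inversion; MC9, a mast cell line; and MC9 cells with an shRNA against Rad21, a subunit of the cohesin ring. H3K27me3 is the mark left by Polycomb repressive complex 2, and the series title names its response to low levels of transcription as the question. Each cell type had 1 library per antibody, 25 libraries in all, so no difference could be set against a spread between replicates and no test between cell types was made. Reads recovered per library ranged from 1615826 (H3K4me3 in MC9) to 14812803 (H3K4me1 in 32D). For Pol II they numbered 8911286 in 32D, 10906154 in wild-type mast cells, 5255352 in WSH mast cells, 8959536 in MC9 and 3448364 in MC9 shRad21. For H3K27me3 they numbered 12817169, 11146085, 5659024, 9410979 and 5086284 in the same order. The median CpG island held 14, 15, 6, 7 and 5 H3K27me3 reads, so single islands were measured coarsely for this mark, while the median region downstream of an island held 52 to 164 Pol II reads. Intervals given with read ratios are exact 95% intervals, cover counting error only, and compare libraries, not conditions. Ratios written as log2 are of signal plus a pseudocount, which understates differences of weakly covered genes.

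In wild-type mast cells, H3K27me3 was high at the islands of many developmental regulators and on the whole highest at islands whose genes carried little Pol II, and lower at islands of genes with more Pol II or with hardly any. The highest island belonged to Sim1, a transcription factor of the developing hypothalamus and kidney (mm10 chromosome 10, 50894042 to 50901352), with a signal of 18.9, 599 reads, and a Pol II signal of 0.531 downstream. Next came Lhx2, a LIM homeobox factor (17.5, Pol II 1.06), Scpep1 (16.7, Pol II 0.735), Osr2, a factor of palate and limb development (16.3, Pol II 3.22), and Rsrc1 (15.7, Pol II 1.30). With all 9322 islands ranked by Pol II downstream into 20 bins, the median H3K27me3 signal was 0 in bin 1 and 1.17 in bin 2 (median Pol II 0.219). It was 2.21 in bin 3, 2.70 in bin 4 and 3.05 in bin 5 (interquartile range 1.69 to 4.98, median Pol II 0.525). Beyond that it was 2.83 in bin 6, 1.18 in bin 10 and 0.394 in bin 20 (median Pol II 9.22). Spearman's rho across islands was −0.31, and the islands are not independent replicates. The 298 islands on chromosomes X and Y held no read in any library and filled much of bin 1. Without them the 9024 autosomal islands gave a lowest-bin median of 0.788, a highest median of 3.11, again in bin 5, a top-bin median of 0.403 and a rho of −0.43.

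The other cell types did not share 1 profile. WSH mast cells resembled the wild type, with Sim1 (18.9), Rsrc1 (17.0), Lhx2 (16.6), Igf2bp3 (15.6) and Bcat1 (15.4) highest, a top median of 2.27 in bin 5 and a rho of −0.28. In the lines the highest islands included genes with ample Pol II and H3K4me3, the mark of active promoters. In 32D these were Glo1, which encodes the detoxifying enzyme glyoxalase 1 (16.9, Pol II 7.15, H3K4me3 160), Eif3e, a translation initiation factor subunit (16.5, Pol II 9.43), and Fuk (15.7). Their H3K27me3 reads stood lower, at 11.7, 5.52 and 4.99 times the genome mean, against 18.3 at Sim1 in wild-type mast cells. The islands of 2610005L07Rik (18.9) and 6820431F20Rik (16.9) are listed as high too, but no 2 kb bin overlaps them, so no reads could be recovered to check these values. In MC9 they were 9630033F20Rik (18.9, Pol II 12.3), Gabarapl1, an autophagy gene (18.3, Pol II 44.2), Bcat1 (16.7, Pol II 0.835), Fuk (16.0, but 3.32 times the genome mean in reads) and Parp11 (15.4, Pol II 32.2). In MC9 shRad21 they were Gabarapl1 (18.9), 9630033F20Rik (18.8), Parp11 (16.5), the cyclin gene Ccnd2 (15.5) and 1700039E15Rik (11 reads). Several of these islands lay where every antibody had more reads, as counted after the values were seen within 120 kb of the island, leaving out the island and 4 kb at each side. In MC9, reads of the 5 antibodies stood there at 13.7 to 19.3 times the genome mean around 9630033F20Rik and Ccnd2, 7.95 to 13.5 around Parp11 and 4.38 to 21.4 around Gabarapl1. In MC9 shRad21 they stood at 9.38 or more around these 4 genes, and in 32D, wild-type and WSH mast cells at 3.36 or less. Around Glo1 they stood at 4.01 to 4.69 in 32D and at 2.86 or less elsewhere. The H3K27me3 libraries of the lines were less enriched at islands, with 1.32% of reads in island bins in 32D, 0.997% in MC9 and 1.10% in MC9 shRad21, against 2.46% in wild-type and 2.25% in WSH mast cells. The 99th percentile of islands lay at 3.45, 3.15 and 2.67 times the genome mean, against 9.64 and 9.37. The bin medians were flatter in these 3 libraries. The highest was 1.41 in 32D, in bin 18, 1.39 in MC9, in bin 5, and 0.894 in MC9 shRad21, in bin 8. Their top-bin medians were 1.20, 0.452 and 0.475. Spearman's rho was 0.36 in 32D, −0.07 in MC9 and 0.14 in MC9 shRad21, and on autosomes alone 0.30, −0.16 and 0.07. Pol II and H3K4me3 went together in every cell type, with a rho of 0.77 in 32D, 0.73 in wild-type mast cells, 0.71 in WSH mast cells, 0.74 in MC9 and 0.73 in MC9 shRad21.

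**Figure D1:**
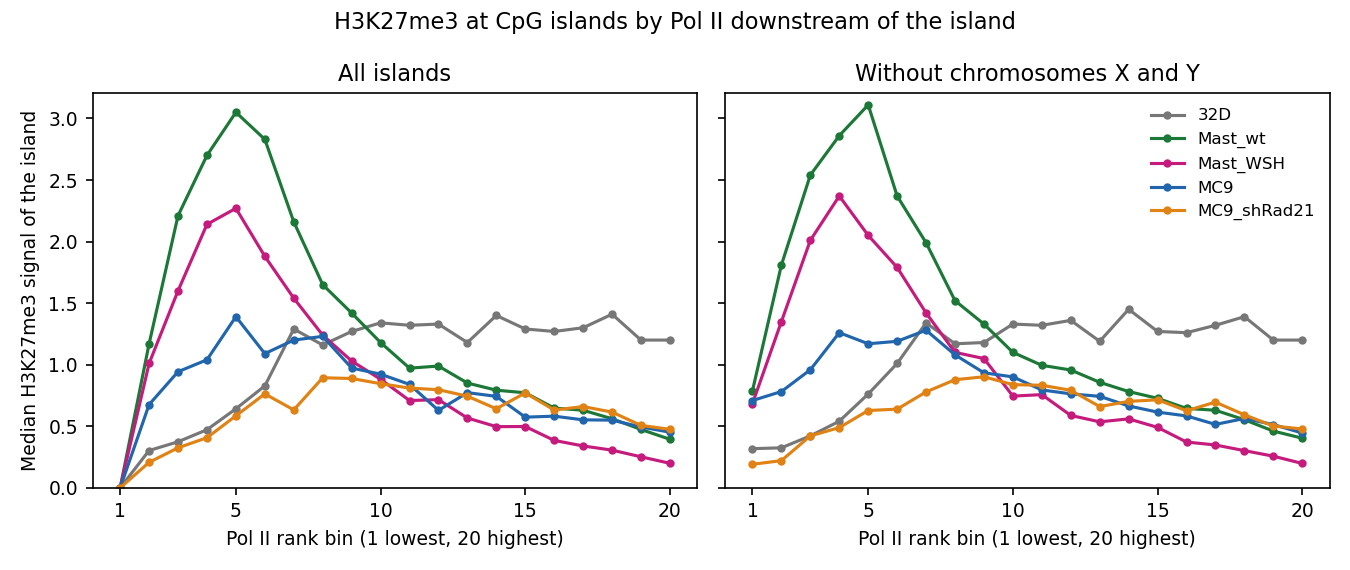
Median H3K27me3 signal of CpG islands (vertical axis) in 20 bins of Pol II signal downstream of the island (horizontal axis, 1 lowest), 1 line per cell type. The first panel holds all 9322 islands and the other the 9024 on autosomes. Signal is on the scale of the reference library, wild-type mast cells. The curve of wild-type mast cells tops out at 3.05 in bin 5 of the first panel and at 3.11 in bin 5 of the other, that of MC9 shRad21 at 0.894 and 0.902.

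Comparing wild-type mast cells with 32D, Pol II was far higher over mast cell genes. Fcer1a, the ligand-binding chain of the high-affinity IgE receptor, stood at 97.8 against 0.328 (read ratio 243, 104 to 749), the granule protease gene Cpa3 at 89.0 against 0.670 (141, 108 to 189), and Tph1, the enzyme that starts serotonin synthesis, at 59.8 against 0.661. Kit, the receptor for stem cell factor (island at chromosome 5, 75574620 to 75576205), stood at 29.4 against 0.172 (log2 5.15, read ratio 153, 114 to 209), and Il1rl1, the interleukin-33 receptor, at 55.6 against 0.162, 447 reads against 1. H3K27me3 was at least 2-fold higher at 71 of 71 developmental genes, where the 32D library was also less enriched over islands as a whole (99th percentile 3.45 against 9.64). Among them were Barhl2, a neural homeobox gene (10.6 against 0.0173, read ratio 200, 35.4 to 7948), Gata6, a factor of endoderm and heart (8.85 against 0.103, read ratio 55.6, 18.6 to 273), Zic4 (9.22 against 0.154) and Sox9, a factor of cartilage and gonad (8.73 against 0.154).

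Of 33 measured mast cell genes, 27 had at least 2-fold more Pol II in wild-type mast cells and 0 had at least 2-fold less (median log2 2.55, above all of 10000 random lists of matched level). For H3K4me3, 19 had more and 0 less (median 2.80, percentile 100). Blood progenitor genes had 3 higher and 0 lower of 22 (median 0.66, percentile 100), with Meis1, a homeobox factor of stem cells, at 12.6 against 0.258 and the surface marker Cd34 at 7.33 against 0.559. Erythroid and megakaryocyte genes had 6 higher and 2 lower of 16 (median 0.54, percentile 99.53, with reads 0.27 and 95.24), with the globin gene Hbb-bt at 6.78 against a listed 0. Cell cycle genes lay lower, 0 higher and 7 lower of 30 (median −0.66, percentile 0.00), among them the replication helicase genes Mcm5 (1.75 against 7.46) and Mcm6 (2.79 against 9.15) and the topoisomerase gene Top2a (4.50 against 14.0). Outside the lists, the highest ratios included Cish, an inhibitor of cytokine signalling (43.9 against 1.14), Igfbp5 (11.8 against 0.159), Fam105a (read ratio 30.3, 15.8 to 66.9) and Il10ra, the interleukin-10 receptor (19.9 against 0.980). The lowest were Slc22a17 (0.218 against 11.5), Arl14ep (1.83 against 17.5), the corticotropin receptor Mc2r (0.228 against 5.17), and Ddx25 (0.624 against 7.61). The integrin Itga4 (1.45 against 12.7) and Zbtb16, a zinc finger factor of progenitors (0.579 against 7.08), followed. Neutrophil and monocyte genes went both ways, 5 higher and 2 lower of 29 (median 0.04, percentile 67.88). The granulocyte factor Cebpe stood at 1.10 against 10.4 and the collagenase Mmp8 at 8.09 against 0.527. Genes of T and natural killer cells (median 0.16), B cells (−0.08), macrophages and dendritic cells (0.06), basophils and eosinophils (0.12), stroma and endothelium (0.17), interferon response (0.24), housekeeping (−0.19), Polycomb machinery (−0.12) and cohesin (−0.30) lay between percentiles 14.99 and 95.72. The 37 genes around Kit on chromosome 5 had a median of 0.30 (percentile 99.74).

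Over all features above the filter, Pol II was 2-fold higher at 502 and lower at 399 of 5307, and H3K27me3 2-fold higher at 1999 and lower at 1811 of 6218. Reads scaled by library gave another split for H3K27me3, 2205 higher and 441 lower of 6896, and moved the median of all islands from −0.10 to 0.33. For H3K4me3 the deposited signal gave 548 higher and 149 lower of 4418 and the reads 266 and 1309, with medians of 0.16 and −0.59. The developmental list had a median log2 of 2.89 in H3K27me3 (percentile 100, random lists 1.05) and 2.72 from the reads. Its genes held more Pol II too, 5 higher and 1 lower with 59 below the filter in both (median 0.68, percentile 100, median signal 0.719 against 0.225). Other islands higher in H3K27me3 and listed at 0 in 32D were those of the chemokine Cxcl12 (10.1, 90 reads against 0), Lipg (9.60), Ripply3 (9.33), Dpysl5 (8.89) and the DNA demethylase Tet1 (7.62). The last 4 held 7, 37, 18 and 7 reads in 32D, with read ratios of 10.2, 5.07, 8.75 and 9.04. The lowest against 32D were Glo1 (0.331 against 16.9), Mtch1, Gm13710, Itm2c and Scin, and reads at Mtch1 and Scin were 5.09- and 3.73-fold fewer. Hoxa9, a homeobox gene of blood progenitors (14.0 against 1.24, read ratio 11.0, 7.22 to 17.6), the Fc receptor gene Fcgr3 (12.9 against 0.161) and the cyclin gene Ccnd1 (10.7 against 0.597) were also higher. Housekeeping genes were lower in H3K27me3 (median −0.50, 0 higher and 6 lower of 26, percentile 0.02). Kit itself had an H3K27me3 signal of 0.616 against a listed 0, 9 reads against 5, a difference not detectable at this depth (read ratio 2.07, 0.623 to 7.86). Of 10733 distal H3K27ac bins in wild-type mast cells, 6620 (61.7%) were gained over 32D, and 5337 (56.5%) of 9449 in 32D were lost. Of those gained, 666 lay within 2 kb of a gene's 5′ end, since distal here means away from CpG islands, and 23 lay around Kit.

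The MC9 line differed from 32D at many of these genes. Pol II over Kit stood at 27.9 against 0.172 (log2 5.07, read ratio 114, 85.6 to 156), over Fcer1a at 76.2 against 0.328 (read ratio 151, 64.4 to 466) and over Cpa3 at 42.6 against 0.670. Interferon response genes lay higher, with the ubiquitin-like Isg15 at 18.6 against 1.66 (read ratio 9.06, 5.56 to 15.7), Irf7 at 20.1 against 5.43 and Oasl1 at 5.12 against 0.870. Over Gng12, a G protein subunit, Pol II stood at 0.278 against 15.6 (48.5-fold fewer reads, 40.6 to 58.5), over the fucosyltransferase Fut8 at 0.417 against 15.9 (35.3-fold, 31.7 to 39.4) and over the kinase Cdk6 at 0.335 against 8.30 (22.0-fold, 19.1 to 25.3).

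Of 33 mast cell genes, 20 were at least 2-fold higher in Pol II and 1 lower (median log2 1.43, percentile 100), and of 20 interferon genes 9 were higher and 1 lower (median 0.95, percentile 100). Progenitor genes had 5 higher and 2 lower of 22 (median 0.30, percentile 98.39, with reads 0.06 and 89.18), with Mycn, a proto-oncogene, at 0.254 against 20.6. Housekeeping genes had 0 higher and 5 lower of 26, but did not stand apart from random lists (median −0.21, percentile 23.76, with reads −0.56 and 11.50). The other genes at the top were Il1rl1 (20.6 against 0.162), Igfbp5 (20.5 against 0.159), the adhesion gene Cadm3 (16.9 against 0.427), the aryl hydrocarbon receptor Ahr (13.5 against 0.277, read ratio 44.5, 30.7 to 67.3) and Parp11 (32.2 against 1.58), around which every antibody had more reads in MC9. Itga4 (0.513 against 12.7), Zbtb16 (0.208 against 7.08) and Slc22a17 (0.712 against 11.5) were again among the lowest. Of the myeloid genes, Cebpe was listed at 0 against 10.4 and Ms4a3 stood at 5.19 against 28.9, while the interleukin-5 receptor Il5ra stood at 10.2 against 0.477. Among 71 developmental genes, 5 were higher and 1 lower (median 0.17, percentile 99.99), with Pax3, a factor of neural crest and muscle, at 4.15 against 0.212 (read ratio 14.7, 11.7 to 18.7). Cyclin D2, Ccnd2, around which the same holds, stood at 92.1 against 6.67, and the cell cycle inhibitor Cdkn2a at 0.0149 against 2.01.

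Pol II was 2-fold higher at 529 and lower at 477 of 5358 features, against 414 and 637 of 5511 with reads, which moved the median of all features from −0.07 to −0.24. H3K27me3 was 2-fold higher at 1354 and lower at 1992 of 5681 islands, against 301 and 1254 of 5744 with reads (medians −0.28 and −0.49), and H3K4me3 at 450 and 402 of 4146 against 612 and 354. The developmental list was higher in H3K27me3 in MC9, with 20 genes higher and 1 lower (median 0.69, percentile 100, reads 0.55), at a median signal of 1.14 against 0.534. Single islands with higher H3K27me3 were those of the phosphatase Ptpn13 (8.41 against a listed 0), Fam83d (8.22 against a listed 0, but 28 against 18 reads, ratio 2.12, 1.13 to 4.07), Dpysl5 (7.99 against a listed 0, but 30 against 18 reads, ratio 2.27, 1.22 to 4.32) and the semaphorin receptor Plxna2 (8.49 against 0.147, read ratio 5.86, 2.90 to 13.1). The kinase gene Pak6 stood at 7.27 against a listed 0, but its 8 and 6 reads show no detectable difference at this depth. Dnajc18, Angptl4, Tmem109, Atp6v1c1 and Mks1 were listed at 0 in MC9 and stood between 9.89 and 10.8 in 32D, although the interval of Mks1 (6 against 20 reads, ratio 0.409, 0.134 to 1.05) included 1. At Kit, H3K27me3 reads numbered 6 and 5, too few to show a difference (ratio 1.63, 0.416 to 6.77). Of 9992 distal H3K27ac bins in MC9, 6635 (66.4%) were gained over 32D, 25 of them around Kit, and 5640 (59.7%) of 9449 in 32D were lost.

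**Figure D2:**
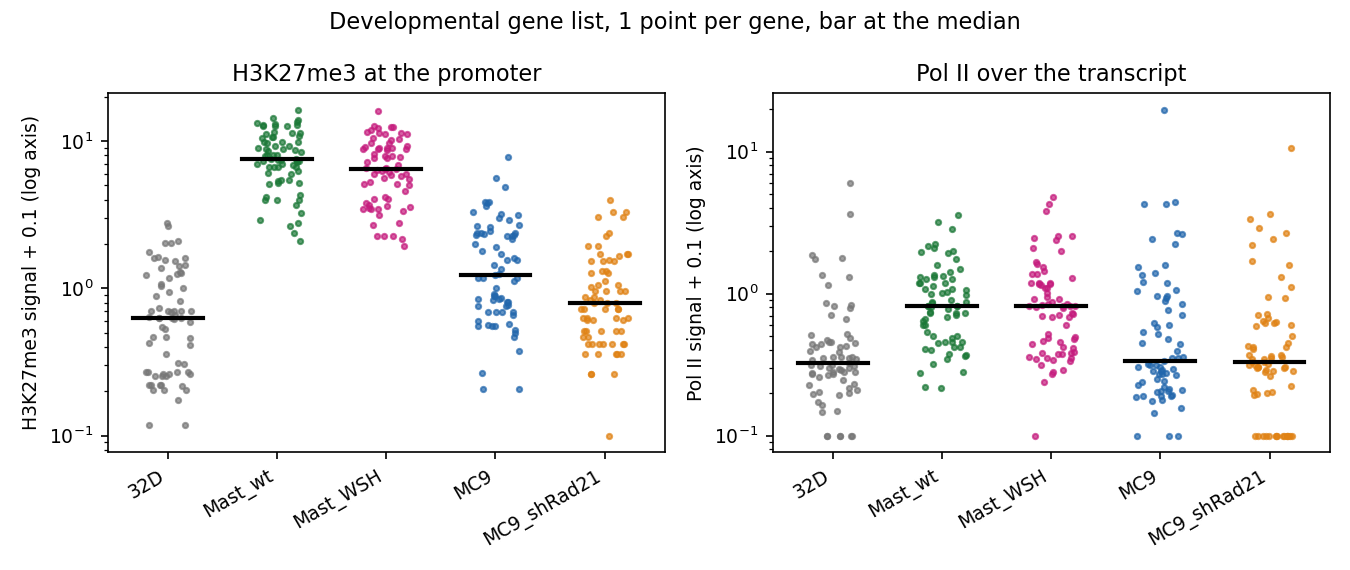
H3K27me3 signal at the promoters (first panel) and Pol II signal over the transcripts (other panel) of 71 developmental genes in 5 cell types, on log axes, with 1 point per gene and a bar at the median. The H3K27me3 medians are 0.534 in 32D, 7.45 in wild-type mast cells, 6.41 in WSH mast cells, 1.14 in MC9 and 0.701 in MC9 shRad21, each drawn with 0.1 added.

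WSH mast cells differed from wild-type mast cells most of all at Kit. Pol II over Kit was 0.304 against 29.4, 30 reads against 8594 (log2 −4.94, 138-fold fewer after scaling, 96.6 to 205), the lowest ratio of all islands. H3K4me3 at its island was listed at 0 against 75.5 (5 reads against 619), and H3K27me3 reads there numbered 40 against 9 (ratio 8.75, 4.18 to 20.5; deposited signal 1.45 against 0.616). Over the island and gene (chromosome 5, 75572000 to 75657999) H3K27me3 had a mean signal of 2.55 against 0.642. Most mast cell genes lay close to the wild type, although Hdc, which makes histamine, stood at 13.6 against 2.05 (read ratio 9.61, 8.13 to 11.4) and the protease gene Gzmb at 111 against 37.3 (read ratio 3.94, 3.39 to 4.59).

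Upstream of Kit, a 64.0 kb block that begins where H3K27ac of WSH mast cells ends (chromosome 5, 75508000 to 75571999) held H3K27ac reads at 5.77 times the genome mean in wild-type and 0.315 in WSH mast cells. Elsewhere on the chromosome, a 52.0 kb block inside Corin, a serine protease gene (72348000 to 72399999, within the gene at 72300025 to 72504473), held them at 0.360 in wild-type and 11.1 in WSH mast cells, 32 and 1512 reads. In the same block read density of H3K4me1 was 0.617 against 3.20 and of Pol II 0.331 against 1.58 in wild-type and WSH mast cells, while that of H3K27me3 was 1.73 against 0.915. In the adjoining 104 kb of Corin (72400000 to 72503999) H3K27me3 went the other way, 1.59 against 2.95. Pol II there was 0.336 against 0.264. Both blocks, and so the adjoining part, were chosen after their values were seen. Positions follow the reference order, not that of the inverted chromosome. Of the 37 genes around Kit, 0 were 2-fold higher and 1, Kit itself, was lower in Pol II, with a median of −0.02 (percentile 99.33) that turned to 0.21 under quantile normalization and 0.04 with reads.

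**Figure D3:**
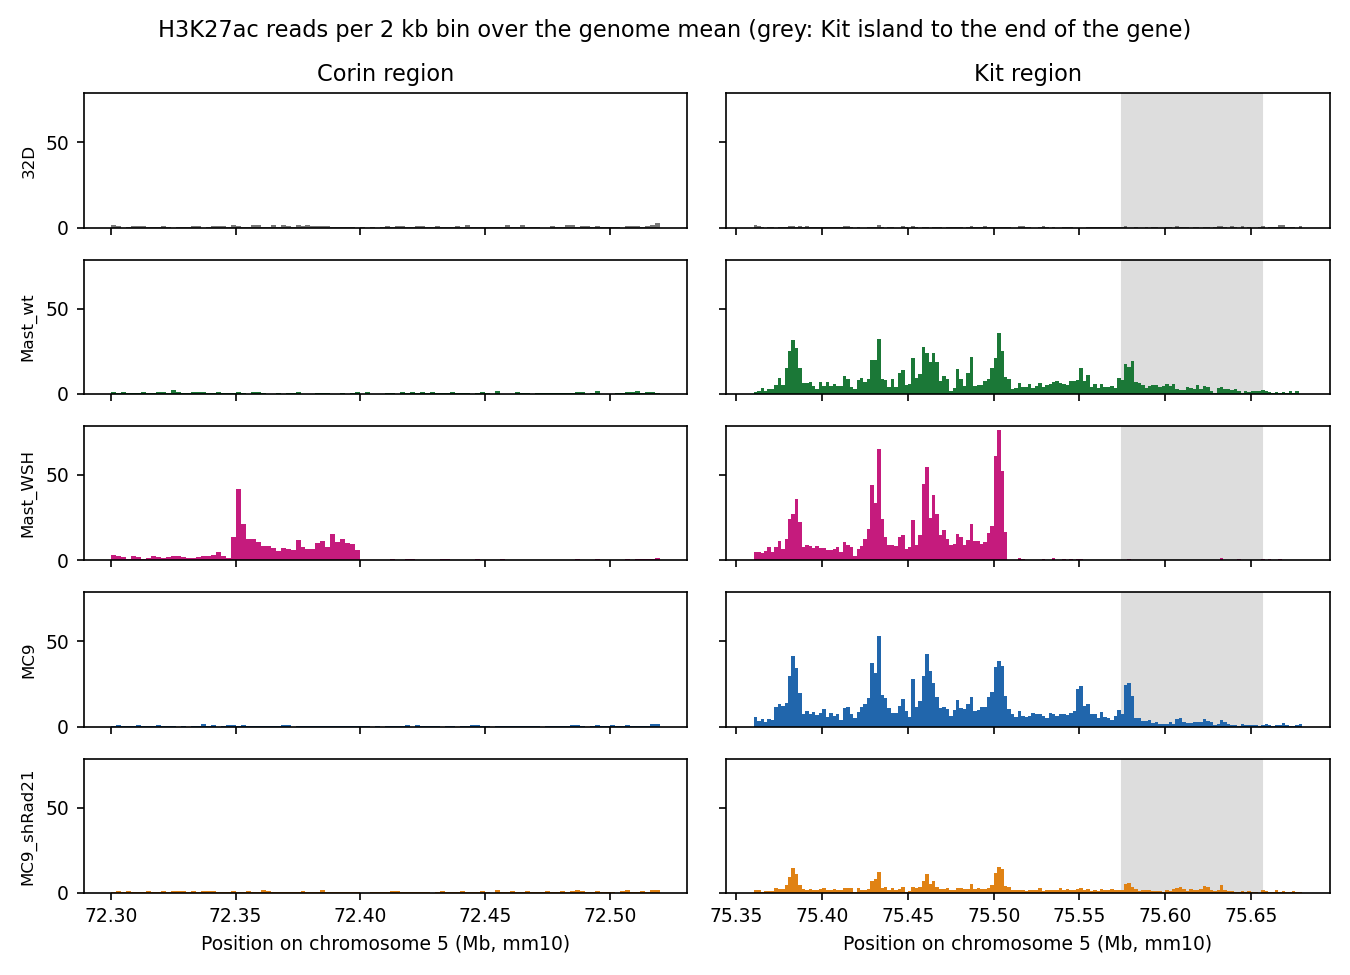
H3K27ac reads per 2 kb bin (vertical axis, 1 shared scale, relative to the genome mean) along the Corin and Kit parts of chromosome 5 (horizontal axis, mm10 position), 1 row per cell type, with Kit shaded grey. The block upstream of Kit averages 5.77 in wild-type mast cells, 8.32 in MC9, 1.86 in MC9 shRad21, 0.330 in 32D and 0.315 in WSH mast cells, and the block within Corin 11.1 in WSH mast cells and at most 0.859 in the other cell types.

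Pol II was 2-fold higher in WSH mast cells at 80 and lower at 37 of 4884 features (reads 152 and 87 of 4862). The highest ratios were at Fam110c (44.5 against 1.47, read ratio 47.7, 31.7 to 75.1), the kinase Sik1 (8.08 against 0.541), and the transglutaminase Tgm2 (28.4 against 3.97). Next were Rabgef1, an exchange factor for small GTPases of the Rab family (15.2 against 3.09), the ubiquitin ligase Mylip (18.3 against 3.90) and the early response receptor Nr4a1 (13.5 against 2.84). The lowest after Kit were at Tma16 (1.63 against 6.48), Igfbp5 (3.98 against 11.8), the homeobox gene Hhex (5.95 against 15.7), Fam3c (2.79 against 7.91) and the Notch modifier Lfng (4.55 against 12.2). The mast cell list had 3 higher and 1 lower of 33, with a median of −0.08 (percentile 66.90) that was 0.36 with reads. Cell cycle genes lay lower (median −0.45, percentile 0.03, reads −0.36), none of 30 by 2-fold, and erythroid genes too (median −0.40, percentile 0.95, with reads −0.11 and 26.21). Of the progenitor genes, Myb stood at 3.93 against 10.7 and Gfi1b at 2.18 against 5.28. H3K27me3 was 2-fold higher at 269 and lower at 911 of 4827 islands, or 74 and 293 of 5953 with reads, where simulated counting noise alone gave 79 and 110. The developmental list was slightly lower (median −0.21, 0 higher and 1 lower of 71, percentile 0.07). Among single islands the rule named Cbr4, 4930452B06Rik, Ston1, Gm15283 and Fanci as higher and Ifngr1, Arhgef10, Slc36a4, Med27 and Tm2d1 as lower. They held 5 to 52 reads, and the intervals of Gm15283, Ifngr1, Arhgef10, Med27 and Tm2d1 included 1. H3K4me3 differed 2-fold at 9 and 4 of 4322 islands. Distal H3K27ac bins numbered 510 gained of 10100 and 1384 lost of 10733, or 3486 gained when bins were called from reads.

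In MC9 shRad21 cells, Pol II over Rad21, the target (chromosome 15, downstream region 51962605 to 51989000), was 5.09 against 5.64 in MC9, with a read ratio of 1.22 (1.02 to 1.46). An shRNA acts on the transcript, so this value does not check the knockdown. Pol II over Kit was 3.86 against 27.9 (log2 −2.65, 5.59-fold fewer reads, 5.03 to 6.24), and H3K27me3 at the Kit island 8.15 against 0.641, 16 reads against 6 (ratio 4.93, 1.83 to 15.4), or 2.14 and 0.434 times the genome mean. The block upstream of Kit held H3K27ac reads at 1.86 against 8.32 times the genome mean, and 22 distal H3K27ac bins around Kit were lost. Pol II was also lower over Gata2, a transcription factor of mast cells and progenitors (10.6 against 48.6, 3.32-fold fewer reads, 2.58 to 4.32), and over Fcer1a (15.4 against 76.2), and higher over the stress factor Atf3 (8.85 against 0.664, read ratio 20.2, 11.3 to 39.2).

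Mast cell genes had 0 higher and 9 lower of 33 in Pol II (median −0.41, percentile 0.52, reads −0.33), and progenitor genes 0 higher and 4 lower of 22 (median −0.42, percentile 0.16). Of the latter, Gfi1b stood at 1.47 against 8.37, the proto-oncogene Myc at 4.79 against 16.6 and Tal1, a transcription factor of blood stem cells, at 8.25 against 25.7. Cell cycle genes had a median of −0.43 (percentile 0.32, with reads −0.10 and 4.25), with the mitotic kinase Plk1 at 0.761 against 2.96. Housekeeping genes lay higher, 3 higher and 0 lower of 26 (median 0.37, percentile 99.76, reads 1.06). The nucleolar genes Ncl and Npm1 stood at 25.8 against 7.83 and at 20.8 against 8.16. Interferon genes had 3 higher and 0 lower of 20 (median 0.32, percentile 99.94), with Oasl1 at 17.9 against 5.12 (read ratio 5.99, 4.96 to 7.26), Mx2 at 3.37 against 1.21 and the RNA sensor Ifih1 at 2.02 against 0.679. None of 11 cohesin genes differed 2-fold (median −0.21, reads 0.05). The lowest other genes were Ccnj (5.19 against 26.1), Lsm4 (0.585 against 4.93), Fam110c (3.79 against 18.9) and Med18, and the highest Cxadr (12.7 against 1.15), Btg3 (16.8 against 2.63), Trib3 (5.70 against 0.754), Arrdc3 (9.81 against 1.79) and the polyamine enzyme Odc1 (7.91 against 1.48). The measured regions of Cxadr (chromosome 16, 78353266 to 78359785) and Btg3 (78359860 to 78373947) adjoin, so reads near their border belong to either.

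The H3K27me3 demethylase gene Kdm6b held more Pol II (16.0 against 6.53, read ratio 3.49, 2.95 to 4.13), the 1 gene of 30 of the Polycomb machinery that was 2-fold higher. In that list 3 genes were lower, with a median of −0.31 (percentile 5.33, reads −0.09). At the developmental list H3K27me3 was lower, 1 higher and 14 lower of 71 (median −0.39, percentile 0.00, reads −0.50). The homeobox genes Gsx2 stood at 0.530 against 3.78 and Hoxc9 at 1.44 against 5.53. The H3K27me3 library of MC9 shRad21 was also flatter over islands as a whole (99th percentile 2.67 against 3.15, median island 0.802 against 0.650). Pol II was 2-fold higher at 190 and lower at 134 of 5016 features, against 490 and 127 of 4923 with reads, which moved the median of all features from −0.02 to 0.13. H3K27me3 was 2-fold higher at 1500 and lower at 1849 of 5118 islands, against 507 and 273 of 5165 with reads (medians −0.28 and 0.27), where counting noise gave 133 and 165. Ptp4a3, Scamp5, Tbl3, Rwdd3 and Donson had the highest H3K27me3 ratios, at 4 to 18 reads, and Alox12, Nipal4, Slc12a7, Ccdc43 and Gm16183 the lowest, of which Ccdc43 had a read ratio of 1.23 and turned direction. The intervals of Ptp4a3, Scamp5, Ccdc43 and Gm16183 included 1. The H3K4me3 library of MC9 shRad21 stood apart: 6.37% of its reads fell in island bins against 32.3% in MC9, and its median island lay 5.20 against 25.7 times above the genome mean. The deposited H3K4me3 signal was 2-fold higher at 321 and lower at 53 of 4280 islands, the reads at 0 and 5436 of 5450, so no direction is given for this mark. Distal H3K27ac bins numbered 1395 gained of 8912 and 1755 lost of 9992 (393 gained when called from reads).

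Between MC9 and wild-type mast cells, Kit differed little, with Pol II at 27.9 against 29.4 (log2 −0.08, read ratio 0.749, 0.724 to 0.775) and 6 against 9 H3K27me3 reads. The MC9 H3K27me3 library was less enriched over islands as a whole (99th percentile 3.15 against 9.64, median island 0.650 against 1.22). Developmental genes held less H3K27me3 in MC9, for example Gata6 (0.276 against 8.85), Six2, a factor of kidney development (0.167 against 7.33), and Pax6, a factor of the eye and brain (0.675 against 11.1). Pol II was lower in MC9 over the protease genes Gzmb (1.10 against 37.3) and Cma1 (2.30 against 36.4) and over Fut8 (0.417 against 13.6, 30.4-fold fewer reads, 27.3 to 34.0). It was higher over Parp11, in a region where every antibody had more reads in MC9 (32.2 against 2.14, read ratio 11.6, 10.3 to 13.1) and Pax3 (4.15 against 0.247, 15.5, 12.5 to 19.4).

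The developmental list had 0 genes higher and 66 lower of 71 in H3K27me3 (median −2.12, percentile 0.00, reads −2.13), and 4 higher and 3 lower in Pol II (median −0.50, percentile 0.00). Mast cell genes had 3 higher and 9 lower in Pol II (median −0.38, percentile 0.00) and progenitor genes 0 higher and 3 lower of 22 (median −0.37), including Mycn (0.254 against 16.0). Interferon genes had 6 higher and 0 lower (median 0.68, percentile 99.99), with Isg15 at 18.6 against 4.47, and cell cycle genes 3 higher and 2 lower (median 0.50, percentile 100), with Ccnd2, around which every antibody had more reads in MC9, at 92.1 against 13.4 and Cdkn2a at 0.0149 against 4.45. The lowest other genes were Nampt, an enzyme of NAD synthesis (1.65 against 19.0), Hemk1 (1.76 against 19.1), Cish (5.06 against 43.9), the clotting factor subunit F13a1 (0.314 against 6.88) and Arhgap20. The highest were 3110039M20Rik (10.2 against 0.278), Fam110c (18.9 against 1.47), 9630033F20Rik, which neighbours Ccnd2 (12.3 against 0.746), Cyp1b1 (11.4 against 0.791) and Hlcs, which attaches biotin to carboxylases (8.03 against 0.688, read ratio 9.99, 9.10 to 11.0). Pol II was 2-fold higher at 183 and lower at 225 of 5039 features (reads 130 and 285 of 5120, median −0.15). H3K27me3 was 2-fold higher at 1086 and lower at 1809 of 5502 islands, and with reads at 64 and 2573 of 5724 (medians −0.25 and −0.91). H3K4me3 was higher at 114 and lower at 387 of 4325, and with reads at 1211 and 111 (medians −0.16 and 0.65). The lowest single islands in H3K27me3 were those of Gm14114, Mgarp, Sdc4, Slc37a1 and Zkscan16, all listed at 0 in MC9. They held 1, 4, 20, 21 and 5 reads there, and those of Sdc4 and Slc37a1 were 3.97- and 4.91-fold fewer than in wild-type mast cells. The highest were those of Slc26a11 (8.74 against a listed 0, read ratio 17.5, 6.47 to 66.2), Ccnd2 (14.6 against 0.423), Fuk (read ratio 2.27), Mrps25 (interval 0.502 to 3.42) and Stk32a. Of 9992 distal H3K27ac bins in MC9, 3554 (35.6%) were gained over wild-type mast cells, and 3690 (34.4%) of 10733 were lost.

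Whether H3K27me3 and Pol II differed together was asked at islands of low and of high mean Pol II, 4661 each. Between wild-type mast cells and 32D the rho of the log2 ratios was 0.09 at low and −0.09 at high Pol II islands, and between MC9 and 32D 0.08 and 0.00. It was 0.02 and −0.06 between WSH and wild-type mast cells, −0.04 and −0.02 between MC9 shRad21 and MC9, and −0.01 and −0.14 between MC9 and wild-type mast cells. The same ratios of Pol II and H3K4me3 gave 0.37 and 0.54, 0.40 and 0.56, 0.14 and 0.23, 0.09 and 0.13, and 0.27 and 0.35 in the same order. These values are across islands, which are not independent replicates, and comparisons that share a library are not independent of each other.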

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

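Recovered reads, leaving out chromosomes X and Y, islands with every bin covered and the subtracted 4 Mb level were chosen only after results were seen; the other settings were planned. No paired analysis was possible because each group had 1 library and no test was made. Depth limits H3K27me3 most: the median island held 5 to 15 reads, and intervals of several islands named include 1. Of 2-fold H3K27me3 counts from reads, the 74 islands higher in WSH than wild-type mast cells (noise 79) and the 64 higher in MC9 than wild-type mast cells (noise 48) lay near counting noise, and the other H3K27me3 counts above it. Single-gene and list values kept their direction and size at 319 results under quantile normalization (28 moved, 5 reversed), 278 with reads (68 moved, 6 reversed) and 87 with the smaller pseudocount (25 moved). The other results, within and between cell types, did so at 47 (3 moved), 37 (22 moved, 1 reversed) and 26 (4 moved) under those settings. They did so at 19 without the filter (1 moved) and 15 with Pol II over the island (3 moved, 2 reversed). Over the whole transcript 9 did so (1 moved), and with islands split in 3, 8 (1 moved, 1 reversed). Without X and Y 13 did so (7 moved), and with the regional level subtracted 6 (3 moved, 1 reversed). With only islands above 0 it was 4 (5 moved, 1 reversed), and with every bin covered 3 (7 moved). With the top 0.5% of H3K27ac all 5 moved. The tolerances were set after the data were seen: 0.05 in rho, 1.5-fold in counts and list medians, and 1 rank bin. For single genes it was the read interval's width on either side divided by 2, or 1.5-fold where that interval was open. For the values that follow the cause was not tested, except where the setting itself removes features.

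With Pol II taken over the island, the rho of H3K27me3 and Pol II was −0.24 in wild-type mast cells and 0.00 in MC9, which lost its sign, and the highest median of 32D lay in bin 20. The rho of differences between MC9 and wild-type mast cells was 0.05 at low Pol II islands, a reversal, and −0.07 at high ones. Over the whole transcript the highest median of MC9 shRad21 lay in bin 11. With only islands above 0, rho was 0.24 in 32D (highest bin 13), −0.47 in wild-type and −0.43 in WSH mast cells, −0.20 in MC9 and −0.01 in MC9 shRad21, a reversal. Leaving out X and Y, and likewise keeping only islands with every bin covered, gave 0.30 in 32D (highest bin 14), −0.43 in wild-type and −0.39 in WSH mast cells, −0.16 in MC9 (highest bin 7) and 0.07 in MC9 shRad21; both settings remove islands without reads. With reads the highest bin of 32D was 7 and the rho of MC9 was −0.20.

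With reads, H3K27me3 was 2-fold lower at 441 islands between wild-type mast cells and 32D, higher at 301 and lower at 1254 between MC9 and 32D. It was higher at 74 and lower at 293 between WSH and wild-type mast cells, higher at 507 and lower at 273 between MC9 shRad21 and MC9, and higher at 64 between MC9 and wild-type mast cells. Pol II was 2-fold higher at 152 and lower at 87 features between WSH and wild-type mast cells, and higher at 490 between MC9 shRad21 and MC9, where 6 lists by mark stood apart in place of 11. Log2 ratios at Kit with reads were 2.30 for H3K27me3 between WSH and wild-type mast cells, −2.31 for Pol II between MC9 shRad21 and MC9, and −0.41 for Pol II and −0.16 for H3K27me3, a reversal, between MC9 and wild-type mast cells. Distal H3K27ac bins gained were 3486 between WSH and wild-type mast cells and 393 between MC9 shRad21 and MC9. The rho of differences was −0.18 at high Pol II islands between wild-type mast cells and 32D, 0.16 at low ones between MC9 and 32D, and −0.19 at high ones between MC9 and wild-type mast cells. Rad21 in Pol II (0.26) and Ccdc43 in H3K27me3 (0.22) reversed between MC9 shRad21 and MC9.

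The smaller pseudocount, by construction, raised the size of the Kit Pol II ratio to 5.92 between wild-type mast cells and 32D, 5.85 between MC9 and 32D and −5.58 between WSH and wild-type mast cells, and counted 63 features 2-fold lower in the last comparison. Without the filter H3K27me3 was 2-fold lower there at 1496 islands, since more islands are counted. Quantile normalization gave 2148 islands 2-fold higher in H3K27me3 between MC9 and 32D, 843 between WSH and wild-type mast cells and 1860 between MC9 and wild-type mast cells. It reversed the Pol II medians of the developmental list (0.24) and of the genes around Kit (0.21) between WSH and wild-type mast cells. In H3K4me3 the cell cycle list reversed between MC9 shRad21 and MC9 (−0.25 under quantile normalization, −2.38 with reads) and between MC9 and wild-type mast cells (0.37 and 1.00), as did interferon genes in the last comparison (0.61 and 1.03), and with reads the cohesin list between WSH and wild-type mast cells (0.04). With islands split in 3, the rho of differences at low Pol II was 0.17 between wild-type mast cells and 32D and 0.09, a reversal, between MC9 and wild-type mast cells. Subtracting the regional level gave 0.01 between wild-type mast cells and 32D, 0.14 between WSH and wild-type mast cells and 0.03, a reversal, between MC9 shRad21 and MC9 at low Pol II, and −0.07 at high Pol II between MC9 and wild-type mast cells. With the top 0.5% of H3K27ac, which by construction holds fewer bins, 3539, 3617, 238, 728 and 1825 distal bins were gained in the 5 comparisons, in the order of the report.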

Other observations

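A stretch of chromosome 6 that holds 9630033F20Rik and the cyclin gene Ccnd2 (127000000 to 127239999, 240 kb, chosen after its values were seen) carried more reads in the MC9 and MC9 shRad21 libraries of every antibody. Read density over the genome mean was 14.6 to 20.9 in MC9 and 16.5 or more in MC9 shRad21, against 0.812 to 1.66 in 32D, 1.32 to 3.00 in wild-type and 1.24 to 2.48 in WSH mast cells. The sequence around Parp11 and Gabarapl1, farther along the chromosome, held more reads of every antibody in both cell types too, at 7.95 or more around Parp11 and 4.38 or more around Gabarapl1. The Pol II, H3K4me3 and H3K27me3 values given for these 4 genes in MC9 and MC9 shRad21 include this regional level.

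Genes near Kit, and Corin farther from it on the same chromosome, carried H3K27me3 of their own in mast cells. They were chosen for this paragraph after their values were seen. The promoter of Kdr, a receptor of endothelial cells, stood at 0.257 in 32D, 7.08 in wild-type mast cells, 7.35 in WSH mast cells, 1.54 in MC9 and 1.22 in MC9 shRad21. In the same order, Gsx2 stood at 1.16, 10.4, 11.1, 3.78 and 0.530, and Corin at 0.844, 4.82, 5.47, 0.735 and 2.10. Chic2 stood at 1.22, 2.56, 0.714, 1.09 and 0.883.

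Of the tests that follow, those on shared top bins and on flanking sequence were set before their results were seen, and the others only after. H3K27me3 at developmental promoters was lower in 32D, MC9 and MC9 shRad21 than in wild-type mast cells. The adjustment of values cannot be the whole cause, since unadjusted reads at these promoters differed at least 6.44-fold at the median. Housekeeping promoters held at least 0.962 times the wild-type reads. This cannot exclude a loss of CpG-rich DNA, since their wild-type median signal was only 0.488 and higher background could hide it. The median island lay at 0.955, 0.650 and 0.802 times the genome mean in 32D, MC9 and MC9 shRad21. It lay at 1.22 in wild-type and 0.961 in WSH mast cells. A complete failure of the immunoprecipitation is argued against by the top 1% of bins away from islands, of which at least 11.1% were shared with wild-type mast cells where chance gives 1%. However, WSH mast cells shared 65.4% and sequence-dependent background common to all libraries also adds to such shares. Weaker enrichment in these libraries, a loss of CpG-rich DNA, and a biological difference between lines and primary cells stay open, and each could give the pattern.

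In wild-type mast cells H3K27me3 was highest at islands with little Pol II and lower at those with the least. Regions where no read can be placed are argued against as the whole cause, since with fully covered islands the lowest bin still had 0.255 of the highest median. Local background shared by the Pol II and H3K27me3 libraries cannot be told apart from the pattern. Among 2252 islands with the least Pol II, rho of H3K27me3 reads and Pol II was 0.38. After dividing by flanking sequence it was 0.10, at the bound set for it. In WSH mast cells, whose profile was similar, these values were 0.29 and 0.04. They were 0.43 and 0.09 in 32D, 0.20 and 0.15 in MC9, and 0.26 and 0.14 in MC9 shRad21. A response of the mark to low transcription may be part of the pattern. At Kit, WSH mast cells, which carry a chromosomal inversion, and MC9 shRad21 held less Pol II and more H3K27me3 reads (ratios 8.75 and 4.93). In 32D, with hardly any Pol II at Kit, its island held 5 H3K27me3 reads. In that library the median developmental promoter held 11.7-fold fewer scaled reads than in wild-type mast cells. The 5 reads thus cannot tell an unmarked island from weak enrichment of the library. Across low Pol II islands the rho of differences ran from −0.04 to 0.09 under the main setting. With islands split in 3 it was 0.17 between wild-type mast cells and 32D. Other settings reversed its sign between MC9 shRad21 and MC9 and between MC9 and wild-type mast cells. With 1 library each, these comparisons bear on such a response but cannot decide it.

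Kit in MC9 shRad21 held less Pol II and more H3K27me3 than in MC9. Counting noise is argued against by a lower bound of 1.83 on the H3K27me3 read ratio. The Kit ratio lay at percentile 98.4 of 5860 islands with at least 10 reads summed over both libraries, whose median was 1.16. That set takes in islands with fewer reads than Kit, whose ratios scatter more. A general difference between both H3K27me3 libraries thus cannot be told apart. Nor can a mixture of cells with and without Kit transcription, as Pol II stood at 13.8% of MC9 and the mark in silent MC9 cells was not measured. An effect of the shRNA against Rad21 could also account for it, and was not tested with 1 library each.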
